A study of Rattus norvegicus with 2 samples.

How the data were processed

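Total RNA from liver was extracted, converted to biotin-labelled RNA and hybridized to Affymetrix rat arrays, per the labels' protocols. Of the 2 arrays in the series, 1 was from fasted rats and 1 from rats killed 4 h after an oral bolus of olive oil. The groups follow the samples' titles. The labels give neither a number of rats per array nor the hour of the day at which either group was killed.

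The deposited values are 1 signal intensity per probe set and array on a linear scale. Affymetrix Expression Console is named as the tool per the submitters' processing notes; its algorithm, version, target and any filter are not given in the sources used here. The mean signal after trimming 2% of the probe sets at each end was 200.1 on both arrays, which points to a scaling of the intensities to a common level before they were deposited. Such a scaling assumes that the bulk of transcripts does not shift between livers, and a summary of this kind is noisy for dim probe sets. The values carry no detection call, so that presence could not be judged per probe set, and the precision is limited by the number of arrays.

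The 57 control probe sets were used only to describe array quality. For the other 31042, signals below the 25th percentile of all values, 12.8, were raised to it and the log2 was taken, with no further normalization. A probe set counted as measured when its mean log2 signal over both arrays reached the median of all probe sets (5.37, a signal of 41.4), which left 15521. With 1 array per group no test was possible. Differences are olive oil minus fasted, and a fixed size of 2-fold took the place of a threshold on a test.

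Gene symbols came from the platform's annotation, which can be old. Of the probe sets, 20826 had 1 gene, 436 several and 9780 none listed. Symbols were updated by gene ID through a RefSeq gene table of the GRCr8 assembly, which held the IDs of 20758 of the 20826 and was used for names only. A gene was represented by its brightest probe set, and no gene was named from a probe set with several genes. In this way 14217 genes were represented and 9209 were measured.

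Before the data were examined, 30 gene lists were written for liver lipid, glucose and amino acid metabolism, stress and hormone responses, and cell types, with 885 entries, of which 771 matched a gene and 114 were not used here. For each list with at least 5 measured genes, the median log2 difference was placed among 10000 random lists of the same size, drawn to match the mean signal in 10 bins. A median at or below the 2.5th or at or above the 97.5th percentile was called apart. This position describes these 2 arrays and is not a p-value.

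Genes named in the text were fixed by a rule written before the data were examined. It took the 15 highest and 15 lowest differences among measured genes changed at least 2-fold whose measured probe sets all had one sign, passing over symbols that are only placeholders (1 gene). It added up to 4 members of largest difference per list, and 18 regulator and rate-limiting genes whatever their change, of which 13 were analysed. Other genes are marked where they are named.

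The functions were tested on simulated arrays made from the real signal levels with a noise SD of 0.2 on the log2 scale and 200 changed probe sets. This noise is below the scatter of 0.35 between probe sets of one gene and holds no variation between rats, so the test checks the functions and gives no error rate for these arrays. For this comparison of 31042 probe sets, 98% of the 2.5-fold, 96% of the 4-fold and 2% of the 1.5-fold changes were called at 2-fold, and 0 of 15294 unchanged measured probe sets. A list shifted by 0.4 was recovered at 0.40.

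Alternatives set before the data were examined were centring on array medians, quantile and loess normalization, no floor, a floor at the 50th percentile, an offset of 16, no filter on dim probe sets, a filter at the 75th percentile, the mean over a gene's probe sets, leaving out probe sets with shared-transcript suffixes, and thresholds of 1.5-fold and 3-fold. Leaving out genes shared between lists was added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 for loess and matplotlib 3.10.9.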

Results

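Liver RNA of male Wistar rats, an outbred laboratory strain, was measured on 2 Affymetrix rat expression arrays, 1 for fasted rats and 1 for rats that received a bolus of olive oil. Both groups had been fasted for 18 h, and the treated rats were killed 4 h after 5 ml of olive oil, about 16 ml per kg of body weight. The labels do not say whether the fasted rats were kept for these 4 h too. The total time without other food may therefore differ between the arrays. The question behind the design was which liver transcripts differ in the hours when meal fat reaches the blood as triglyceride. Each group was a single array, and the labels do not say how many livers contributed RNA to it. Every difference below therefore compares 2 arrays, has no replicate check and carries no p-value or standard deviation over animals.

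The arrays were similar in overall brightness. The median signal over 31042 probe sets was 42.5 in the fasted array and 44.7 in the olive oil array, and the highest signals were 21843 and 20497. Bacterial transcripts added before hybridization in equal amounts differed little, with a standard deviation of 0.11 on the log2 scale over 18 control probe sets and a range of -0.18 to 0.18. Poly-A control transcripts, which are added to the RNA before labelling, were lower in the olive oil array for 21 of 23 probe sets, with a median log2 difference of -0.22. The ratio of 3' to 5' signal for beta-actin, a sign of RNA integrity, was 2.63 in the fasted and 3.20 in the olive oil array, and for Gapdh it was 1.28 and 1.34. Where a gene had several measured probe sets, their log2 differences scattered with a pooled standard deviation of 0.35 over 2290 genes, and of 0.23 over 853 genes with brighter probe sets, above the 75th percentile. This scatter covers probe error only, not variation between rats.

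After olive oil, the stress-response gene Gadd45b, the acute phase protein gene A2m and the serine breakdown gene Sds were among the transcripts with the largest increases in signal, while Nrep, the phosphate transporter gene Slc34a2 and the retinoblastoma gene Rb1 were among those with the largest decreases. Of 15521 measured probe sets, 564 were at least 2-fold higher and 466 at least 2-fold lower in the olive oil array, together 6.64%. With the arrays centred on their medians the balance turned, to 475 higher and 570 lower. Within 1.5-fold of each other on both arrays lay 78.6% of the measured probe sets, and the 2 arrays correlated with r = 0.957 across measured probe sets, which are not independent replicates. By gene, 296 of 9209 measured genes were at least 2-fold higher and 269 at least 2-fold lower.

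**Figure D1:**
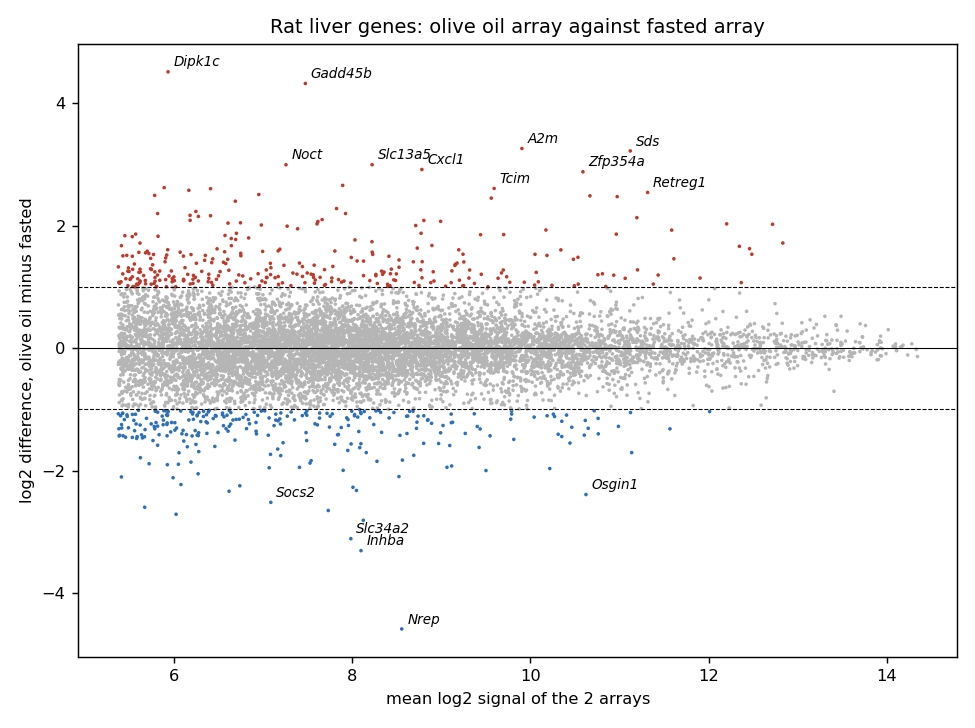
Log2 difference (olive oil minus fasted) of 9209 measured genes against the mean log2 signal of the 2 arrays. Each point is 1 gene, red points are at least 2-fold higher, blue points at least 2-fold lower, and dashed lines mark 2-fold; the 296 red and 269 blue genes lie over the whole range of signal but thin out toward bright genes.

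Among named genes, Gadd45b, a stress-induced growth arrest gene, had a signal of 39.8 in the fasted and 793.6 in the olive oil array, 19.9-fold higher. A2m, the proteinase inhibitor alpha-2-macroglobulin and an acute phase protein of the rat, was 9.56-fold higher. Sds, serine dehydratase, which turns serine into pyruvate, went from 730.6 to 6796, 9.30-fold higher. Slc13a5, a citrate transporter, was 7.96-fold higher, and Noct, a rhythmically expressed gene, 7.95-fold higher. The chemokine gene Cxcl1 was 7.54-fold higher and the zinc finger gene Zfp354a 7.35-fold. Retreg1, a receptor for the degradation of endoplasmic reticulum, stood at 1058 and 6151, 5.81-fold higher. The others of the 15 genes with the largest increases were Rell1, Btg3, Tcim, Trim36, Fabp4 and Faxdc2, between 5.68-fold and 6.30-fold higher, and Dipk1c. Btg3 was dim in the fasted array, and its log2 difference of 2.62 was 1.75 with the floor at the 50th percentile and 2.03 with an offset of 16. Dipk1c was below the floor in the fasted array, so that its size of 22.8-fold higher depends on the floor chosen. Its log2 difference of 4.51 was 2.74 with the higher floor, 3.58 with the offset and 4.92 with no floor.

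Nrep, a gene first described in neuronal regeneration, had the largest decrease, from 1842 in the fasted to 76.9 in the olive oil array, 23.9-fold lower. Inhba, the beta A subunit of activin, was 9.88-fold lower on its brightest probe set, but only -0.18 on the log2 scale on its other measured one, and -1.74 with the mean of its probe sets. The sodium-phosphate cotransporter gene Slc34a2 was 8.63-fold lower and the retinoblastoma gene Rb1 6.27-fold. Socs2, a feedback inhibitor of growth hormone signalling, was 5.72-fold lower, and Osgin1, an oxidative stress-induced growth inhibitor, went from 3611 to 689.7, 5.24-fold lower. The interferon-induced gene Mx2 was 4.68-fold lower. Nckap5l, Relt, Tnfaip8l1, Nim1k, Ifgga2l1, Gucy1b2, Lama3 and Sytl2 completed the 15 genes with the largest decreases, between 4.29-fold and 6.55-fold lower. Of the 15 genes, Relt, Sytl2, Nckap5l, Lama3 and Mx2 were dim in the olive oil array. With the floor at the 50th percentile the log2 differences of Relt, Sytl2 and Nckap5l went from -2.60 to -1.52, from -2.10 to -1.01 and from -2.71 to -1.93. Those of Lama3 and Mx2 went from -2.11 to -1.60 and from -2.23 to -1.74. With an offset of 16 those of Relt and Sytl2 were -1.94 and -1.51. The probe set of Nckap5l can bind transcripts of more than 1 gene by its Affymetrix suffix, and most of the genes in both groups were represented by 1 measured probe set, without a second to compare.

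**Figure D2:**
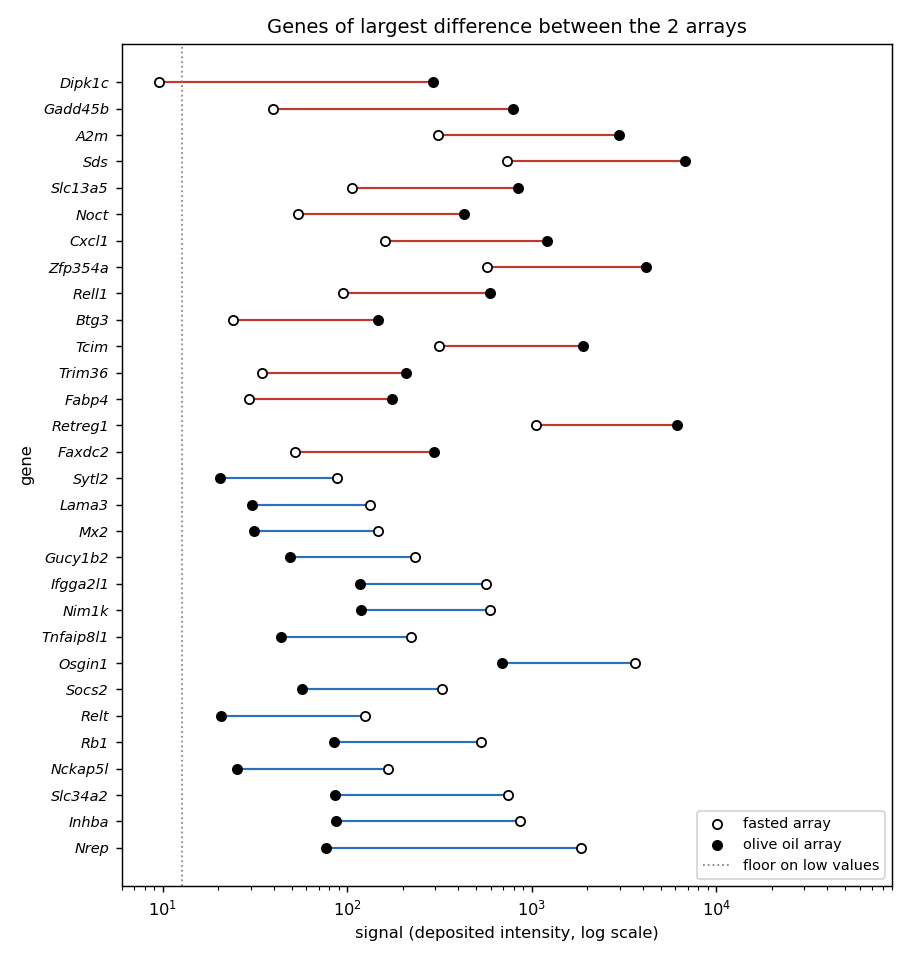
Deposited signal (log scale) of the 15 genes with the largest increases and the 15 with the largest decreases, with open circles for the fasted and filled circles for the olive oil array. Red lines join genes higher after olive oil and blue lines genes lower; the signal of Dipk1c in the fasted array lies left of the dotted floor at 12.8.

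Genes of fatty acid synthesis and desaturation were lower as a list after olive oil, 14 of 21 having a negative difference. Of 21 measured genes of this list, 7 were at least 1.5-fold lower, 3 at least 1.5-fold higher and 11 between, with a median log2 difference of -0.33. Mid1ip1, an activator of acetyl-CoA carboxylase, was 2.95-fold lower, and Fads2, the delta-6 desaturase, 2.62-fold lower. Srebf1, the transcription factor that drives lipogenesis, went from 294.8 to 133.6, 2.21-fold lower, with log2 differences of -1.14 and -1.67 on its 2 probe sets. Fads1 and Scd, also desaturases and named after their values were seen, had log2 differences of -1.10 and -1.02. Against this direction went the 3 genes at least 1.5-fold higher, the highest of them Thrsp, a lipogenic gene, at 2.34-fold. Fasn, fatty acid synthase, differed by 0.28 on the log2 scale. The list's median stood at the 0.11th percentile of 10000 random lists of equally bright genes, and inside their central 95%, at -0.15, when dim probe sets were not filtered out.

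Genes of fatty acid oxidation differed little in size, although 18 of 23 measured members also had a negative difference. None of the 23 was at least 1.5-fold higher and 2 were at least 1.5-fold lower. These were Ehhadh, a peroxisomal beta-oxidation enzyme at 1.97-fold lower, and Bdh1, which makes the ketone body hydroxybutyrate, at 1.70-fold lower. Cpt1a, the gate of mitochondrial fatty acid entry, stood at 4916 and 6030, 1.23-fold higher. Of 31 measured targets of PPAR-alpha, the nuclear receptor that senses fatty acids, 2 were at least 1.5-fold higher and 5 lower. Pdk4, which restrains pyruvate oxidation, was 1.72-fold higher and the lipid droplet gene Cidec 1.76-fold, while Acsl3 was 2.07-fold, Acot1 1.96-fold and Acot3 1.94-fold lower. Angptl4, an inhibitor of lipoprotein lipase, differed by 0.13 on the log2 scale, and the fatty acid transporter gene Cd36 by -0.13. The list medians, -0.07 for oxidation and -0.07 for PPAR-alpha targets, lay inside the central 95% of random lists.

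Genes of triglyceride storage and breakdown went both ways, with 5 of 24 at least 1.5-fold higher and 6 at least 1.5-fold lower. Cidea, a lipid droplet protein, was 3.19-fold higher. Pnpla2, adipose triglyceride lipase, was 2.10-fold higher and Lpin1, a phosphatidate phosphatase, 2.04-fold higher. Gpam, the acyltransferase of the first step of glycerolipid synthesis, was 3.22-fold lower. Plin2, the main coat protein of liver lipid droplets, was bright at 6317 and 8368, but its 2 probe sets disagreed in sign, at 0.41 and -0.21 on the log2 scale. The median of the list, -0.07, was inside the range of random lists, and its mean was 0.0011, on the other side of 0.

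Apolipoprotein genes were nearly equal on the 2 arrays. No member of 26 was at least 1.5-fold higher, and the 2 that were at least 1.5-fold lower were Angptl8, 2.03-fold, and Apobec1, the apolipoprotein B messenger editing enzyme, 1.96-fold. Mttp, which loads lipid onto apolipoprotein B, was 1.32-fold lower. Apoa4 differed by -0.09 and Apob by 0.10 on the log2 scale, the latter with a second probe set at -0.38. Among 20 genes of cholesterol synthesis and uptake, Sqle, squalene epoxidase, was 3.00-fold higher, whereas Dhcr7, the last enzyme of the pathway, was 2.94-fold, Fdft1 1.97-fold and Tm7sf2 1.71-fold lower. The medians of these lists, -0.09 and -0.14, were inside the range of random lists. That of cholesterol synthesis was -0.24 and outside it with a filter at the 75th percentile.

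Genes of bile acid synthesis and transport were lower as a list, with a median log2 difference of -0.16 over 22 genes, at the 1.39th percentile of random lists and inside their range, at -0.14, without a filter on dim probe sets. Of these, 5 were at least 1.5-fold lower, Akr1d1, Amacr, Fgfr4, Cyp8b1 and Nr1h3, and 1 was at least 1.5-fold higher. Nr1h3 was named after its values were seen. Akr1d1 was 3.26-fold lower on its brightest probe set, with 0.01 on another, Amacr 1.75-fold, Fgfr4 1.74-fold and Cyp8b1, the sterol 12-alpha-hydroxylase, 1.54-fold lower. The member that was higher was Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 203.5 and 310.8, 1.53-fold higher.

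Several genes of amino acid breakdown and of the fasting response had a much higher signal after olive oil, while most members of both lists lay within 1.5-fold. Of 43 measured genes of amino acid breakdown and the urea cycle, 9 were at least 1.5-fold higher, 1 was at least 1.5-fold lower and 33 lay between, with a median log2 difference of 0.16, at the 99.98th percentile of random lists. Besides Sds, the amino acid transporter gene Slc38a2 was 3.63-fold higher. Slc25a15, the mitochondrial ornithine carrier, was 3.16-fold and Aass, of lysine breakdown, 3.08-fold higher. Among 31 genes of gluconeogenesis and fasting, 10 were at least 1.5-fold higher, 3 at least 1.5-fold lower and 18 between. Ppargc1a, the coactivator that induces gluconeogenesis, went from 35.0 to 164.2, 4.69-fold higher, with log2 differences of 2.23 and 2.27 on 2 probe sets. It was dim in the fasted array, and its difference of 2.23 was 1.82 with an offset of 16. Got1, the cytosolic aspartate aminotransferase, was 4.08-fold higher. Pck1, the key gluconeogenic enzyme, did not follow, at 12346 and 11140, 1.11-fold lower. Sesn1 was 3.13-fold lower on its brightest probe set and 0.10 on another. The median of this list was 0.13, at the 98.55th percentile. It lay inside the range of random lists after quantile normalization (0.10) or loess (0.11), and at 0.05, the 78.85th percentile, when genes shared with other pathway lists were left out.

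The list that stood farthest from its random lists was that of glucocorticoid-responsive genes. Of 23 measured members, 13 were at least 1.5-fold higher and 3 at least 1.5-fold lower, and the median log2 difference of 0.73, or 1.65-fold, was above all 10000 random lists. Fkbp5, a classical target of the glucocorticoid receptor, was 4.19-fold higher, with log2 differences of 2.07 and 2.11 on 2 probe sets, and the metallothionein gene Mt2A 4.06-fold higher. Tat, tyrosine aminotransferase, was 1.96-fold higher. Gadd45b belonged to this list too, while its relative Gadd45g was 3.55-fold lower. Of the members, 9 were in no other pathway list, and their median was 0.77.

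Immediate early genes went in both directions, 7 of 25 at least 1.5-fold higher and 7 at least 1.5-fold lower, with a median of 0.20 at the 99.48th percentile, which was 0.12 and inside the range of random lists without a filter on dim probe sets. Next to Gadd45b, the highest were Ccn2, connective tissue growth factor, at 4.85-fold, Klf2 at 2.30-fold and Klf4 at 2.27-fold. The log2 differences of Klf2 ranged from 0.16 to 2.79 over its probe sets, and that of Klf4, a dim gene, was 0.80 and under 2-fold with the floor at the 50th percentile. Clock genes also went both ways, with 4 of 18 at least 1.5-fold higher and 3 lower. Usp2, a rhythmic protease gene, was 3.40-fold, the clock output gene Dbp 2.88-fold and Per3 2.39-fold higher, and Bmal1, an activator of the clock, was 1.96-fold lower. The median of this list was -0.07, inside the range of random lists, and its mean was 0.18.

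**Figure D3:**
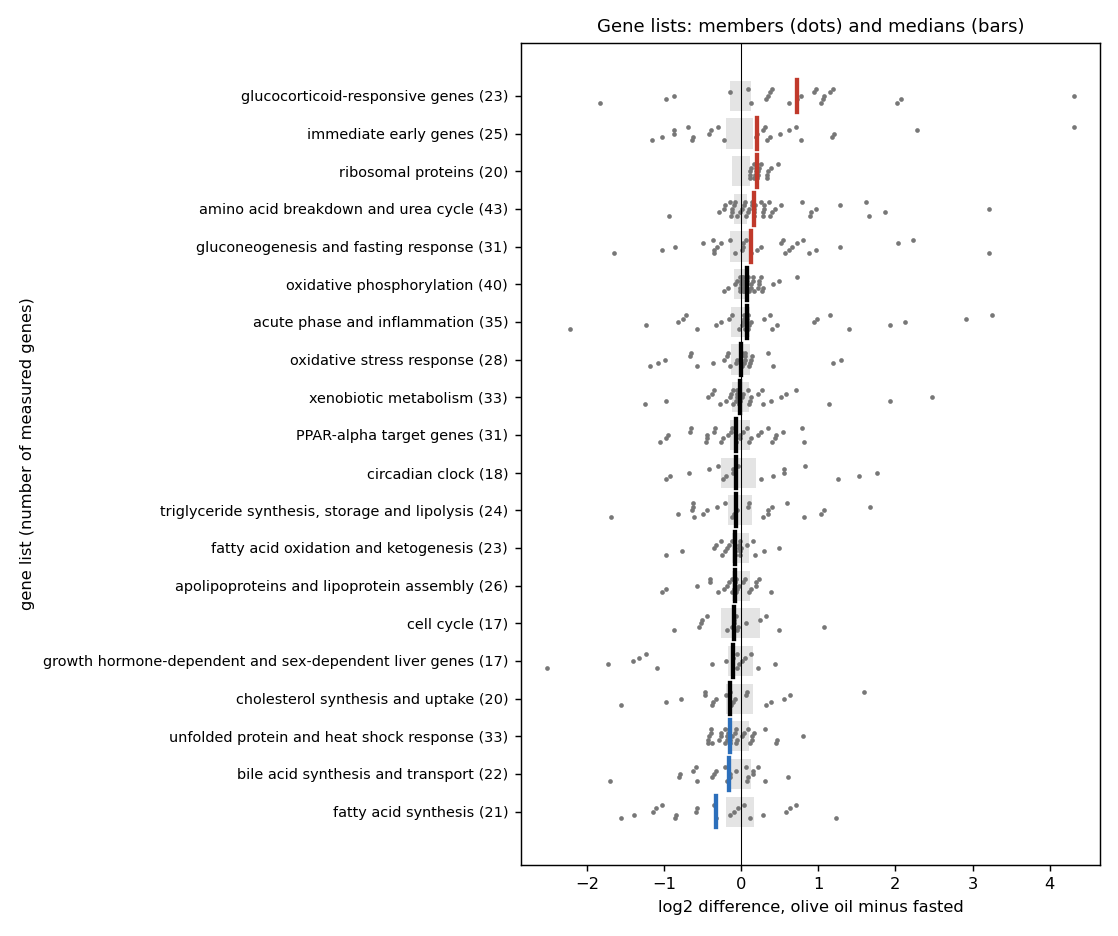
Log2 difference (olive oil minus fasted) of the measured members of each pathway list, 1 dot per gene, with the list median as a vertical bar, red or blue where it lies outside the central 95% of 10000 random lists of equally bright genes and black where it lies inside. Grey boxes span that central 95%; the glucocorticoid-responsive list, with a median of 0.73, stands farthest to the right and fatty acid synthesis, at -0.33, farthest to the left.

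Within the acute phase and inflammation list, a few genes differed widely between the arrays. Of 35 measured members, 8 were at least 1.5-fold higher and 5 at least 1.5-fold lower. Besides A2m and Cxcl1, the interleukin 1 receptor gene Il1r1 was 4.37-fold higher on a bright probe set, with log2 differences between 1.83 and 2.13 on 3 probe sets. Fgb, a fibrinogen chain, was 1.23-fold higher, and Mx2 was lower as given above. The list's median was 0.07, inside the range of random lists, and -0.0029 with the arrays centred on their medians.

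Among 33 xenobiotic metabolism genes, Por, the reductase that supplies electrons to all microsomal cytochromes P450, was 5.55-fold higher, at 854.7 and 4740. Alas1, the first enzyme of heme synthesis, was 3.80-fold and the glucuronosyltransferase gene Ugt2b1 2.21-fold higher, while the sulfotransferase gene Sult1c2 was 2.37-fold lower. All measured P450 genes of the list lay within 1.5-fold, as did 26 of its 33 members, with a median of -0.02, inside the range of random lists, and a mean of 0.13. Genes of the unfolded protein and heat shock response were slightly lower as a list. Of 33 genes, 22 had a negative difference, 32 lay within 1.5-fold, and the median was -0.15, at the 0.74th percentile. With the mean over each gene's probe sets it was -0.12 and inside the range of random lists. Trib3 was the exception at 1.74-fold higher, with log2 differences between 0.26 and 1.34 on 3 probe sets. Dnajb9 was 1.35-fold lower.

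All 20 measured ribosomal protein genes were higher on their brightest probe sets, each by less than 1.5-fold, with a median log2 difference of 0.20, at the 99.95th percentile. The highest were Rps3 at 1.40-fold and Rpl3 at 1.31-fold, the latter with another probe set at -0.12. Oxidative phosphorylation genes were higher in 31 of 40 cases, with a median of 0.07, inside the range of random lists at the 96.52nd percentile, and of -0.0015 with the arrays centred on their medians. Ndufa5 was 1.65-fold and Cox5a 1.40-fold higher. Cell cycle genes, which were dim, had a median of -0.09 over 17 genes, inside the range of random lists. The inhibitor Cdkn1a was 2.10-fold higher and Ccnd1, cyclin D1, 1.83-fold lower.

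Of 17 growth hormone-dependent and sex-dependent liver genes, 6 were at least 2-fold lower and none was at least 1.5-fold higher. Besides Socs2, Cish, another feedback inhibitor of cytokine receptors, was 3.33-fold lower, with log2 differences of -1.73 and -1.49 on 2 probe sets. Cyp2c12 was 2.65-fold lower and the transcriptional repressor Bcl6 had a log2 difference of -1.32. Prlr and Igfals, named after their values were seen, had log2 differences of -1.24 and -1.09. Cyp2c11, a bright male-specific gene also named after its values were seen, differed by -0.05. The median of the list, -0.10, was inside the range of random lists. It was outside with the mean over each gene's probe sets (-0.20) and without probe sets with shared-transcript suffixes (-0.25). Over the 11 measured members in no other pathway list it was -1.09, also outside. That step was chosen after seeing the data, and the 6 members it left out all lay within 1.5-fold.

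Markers of liver cell types were similar on the 2 arrays. The median log2 differences were 0.02 for 14 hepatocyte markers, 0.06 for 14 Kupffer cell and macrophage markers, 0.13 for 15 endothelial markers, 0.16 for 17 stellate cell and fibroblast markers, -0.02 for 7 lymphocyte markers, 0.03 for 6 blood cell markers and 0.17 for 6 markers of intestine, pancreas and adipose tissue. All lay inside the range of random lists, but the stellate cell median was 0.21 and outside it with the mean over each gene's probe sets. Those of hepatocyte, Kupffer cell and blood cell markers turned negative, to between -0.06 and -0.01, with the arrays centred on their medians, and that of hepatocyte markers also after quantile normalization and loess. The 3 measured bile duct markers had a median of -0.03 and were too few for a comparison with random lists. In the blood cell list S100a9, a gene of neutrophils and monocytes, was 4.02-fold and its partner S100a8 2.37-fold higher, the latter at a log2 difference of 0.80 and under 2-fold with the floor at the 50th percentile, and in the last list Fabp4, of adipocytes and macrophages, was 5.96-fold higher. Dcn, a matrix gene of stellate cells, was 1.79-fold higher. Markers of pericentral hepatocytes had a median of 0.16 over 14 genes and those of periportal hepatocytes of -0.08 over 18, with a mean of 0.02, both inside the range of random lists. Cdh1, a periportal marker, was 2.70-fold lower and Hsd17b13 2.07-fold lower, against 9.30-fold higher for Sds in the same list.

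In all, 29 lists had at least 5 measured genes, and the medians of 8 of them lay outside the central 95% of their random lists, 5 higher and 3 lower, where 1.45 would be expected from independent lists of unrelated genes. Lists share genes, and members of a pathway vary together between single livers, so that these positions describe the 2 arrays and not the meal.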

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

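Leaving out genes shared between pathway lists was chosen only after the results were seen. The counts of 564 higher and 466 lower probe sets depended most on the size threshold and the filter. At 1.5-fold they were 1688 and 1628, at 3-fold 133 and 83, without a filter on dim probe sets 1926 and 1600, with a filter at the 75th percentile 197 and 160, and with an offset of 16 in place of a floor 381 and 300. Centring the arrays on their medians, which put the median of measured probe sets at -0.08, turned the balance to 475 higher and 570 lower, 45.5% against 54.8% higher, while quantile and loess normalization left it near 54%. Of the 8 lists that stood apart, amino acid breakdown, glucocorticoid-responsive genes and ribosomal proteins did so under all 10 alternatives set beforehand, with medians of 0.09 to 0.17, 0.62 to 0.75 and 0.13 to 0.21. The other lists lost their position under at least 1. Not all alternatives could move a list, since centring on array medians shifts a list and its random lists together. None of the 29 lists moved into or out of the random range with that centring, no floor, the higher floor or the offset. Gluconeogenesis was inside the random range with quantile (0.10) and loess (0.11) normalization and without shared genes (0.047). Fatty acid synthesis (-0.15), bile acids (-0.14) and immediate early genes (0.12) were inside it without a filter, and the unfolded protein list (-0.12) with the mean over probe sets. Lists that newly stood apart were cholesterol synthesis (-0.24) with the 75th percentile filter, stellate cell markers (0.21) with the mean over probe sets, and growth hormone-dependent genes with that mean (-0.20), without shared-transcript probe sets (-0.25) and without shared genes (-1.09). The causes were not tested. No median of a list that stood apart, and no named gene past 2-fold, changed sign under any alternative. Of 1438 values of named genes under the alternatives, 28 moved by more than the probe set scatter of 0.35, among them 10 under the higher floor and 12 under the offset. No paired analysis was possible because each group was 1 array, and replicates could not be left out. Akr1d1 (-0.85) and Sesn1 (-0.77) were under 2-fold with the mean over probe sets. Lpin1 also was, as it was with Pnpla2 and Cdkn1a under median centring, and Klf4, S100a8, Acsl3, Angptl8, Akr1b8 and Per3 were with the offset. Without detection calls, no limit of signal over background could be set for dim genes.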

Other observations

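The 7 measured interferon-related genes of the acute phase and inflammation list had a lower signal after olive oil, 5 of them by at least 1.5-fold. They were named and grouped after their values were seen, so that the group was not tested. The log2 differences were -2.23 for Mx2, -1.24 for Oas1a, -0.82 for Isg15, -0.75 for Irf1 and -0.71 for Irf7, while Mx1, at -0.33, and Ifit3, at -0.26, lay within 1.5-fold. In the oxidative stress list, with a median of 0.0012 and a mean of -0.09 over 28 genes, and a median of -0.07 with the arrays centred on their medians, Nfe2l2, the transcription factor of the antioxidant response, was 2.11-fold lower. Its target Gclm, of glutathione synthesis, was 2.27-fold lower, in the direction of Osgin1, and Gclc, named after its values were seen, had a log2 difference of -0.98. Srxn1, 2.44-fold higher, and Akr1b8, 2.28-fold higher, went the other way, so the list did not move as one.

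Of the tests below, those of other cell types, of leukocytes, of neutrophils and of the scaling for the acute phase genes were chosen only after the result was seen. The higher signal of glucocorticoid-responsive genes, with a median of 0.73, was not removed by any of 3 other scalings. Under these the lowest median was 0.65, above the upper bound of 0.12 for random lists. Centring on array medians shifts a list and its random lists together, so it could not have removed the pattern. The check shows only that scaling differences were small beside it. More cells of another type would raise their markers, and the highest median of those marker lists was 0.17. Some of these lists pool several cell types, so that a median can miss 1 of them. The blood cell list had a median of 0.03 with S100a9 4.02-fold higher. The test that met its prediction was for a difference in clock phase, on genes chosen before their single values were seen. Output and repressor genes (Nr1d1, Nr1d2, Dbp, Tef, Hlf, Per2 and Per3) had a median of 0.56 and Bmal1, Npas2, Clock, Nfil3 and Cry1 one of -0.67, 1.23 apart. The glucocorticoid pattern may partly reflect livers taken at different hours. The clock gap does not show this, as there is no spread between rats to judge it by. An effect of the oil, a different time without other food, or the handling of the animals may also play a part. Each of these could bear on the clock genes as well as on the glucocorticoid-responsive genes. With 1 array per group, all of these and variation between rats stay open.

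A2m, Cxcl1, Stat3, Il1r1 and Bcl3 were higher under each of the 3 scalings, with a lowest log2 difference of 1.85. All of them were picked for this check after their large increases were seen, so it says little beyond these genes. The median of the whole acute phase and inflammation list was 0.07, inside the range of random lists. More macrophages or lymphocytes in the sample would raise their markers, but the median of 21 such markers was -0.0068 and 0 of them were at least 1.5-fold higher. More neutrophils in the olive oil sample remain open. S100a8 and S100a9 were higher, S100a8 by less than 2-fold (0.80 on the log2 scale) with the floor at the 50th percentile, but 0 other neutrophil genes of the list were measured. An inflammatory signal in hepatocytes, from the meal or from handling, was not tested.

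Socs2 and Cish, at -2.52 and -1.73 on the log2 scale without further scaling, stayed at or below -1.72 under the 3 scalings. That check shows only that scaling differences were small beside these decreases. Growth hormone is released in pulses in male rats, and a liver taken longer after a pulse would be expected to have less Socs2 and Cish and more Bcl6, which the pulses repress. Bcl6 had a log2 difference of -1.32, the opposite of that prediction. It was 1 gene on 1 measured probe set with 1 array per group, so it cannot exclude the timing of pulses. An effect of the meal and variation between rats stay open as well.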
